A study of Mus musculus with 12 samples.

How the data were processed

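RNA from splenic regulatory T cells (Treg), sorted from female C57BL/6 mice, was measured on 12 arrays of a mouse Agilent design with a single dye, Cy3. The labels give 2 genotypes, a conditional knockout of Cd83 (KO) and wild type (WT), and 2 states, non-activated cells (0 h) and cells after 3 h with antibodies to CD3 and CD28. Each of the 4 groups held 3 arrays. The labels name no Cre driver for the knockout. WT mice were 9 weeks old. Of the 6 KO arrays, 4 came from mice of 10 weeks and 2 (replicate 3 at 0 h and replicate 3 at 3 h) from mice of 21 weeks. The series lists 6 mice for the 12 arrays, so some arrays share a mouse, but no label ties an array to a mouse. Per the labels' protocols, amplification started from 20 ng of total RNA for sample 1 at 0 h and from 40 ng for every other sample; which genotype that sample belonged to is not stated. All 6 KO arrays lay on 1 slide, the 3 WT arrays at 0 h on another and the 3 WT arrays at 3 h on another, so 0 of the 3 slides held both genotypes.

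The deposited scanner files hold spot intensity values on a linear scale, 1 file per array, extracted with Agilent Feature Extraction, version 10.7.3.1 per the file headers and version 11 per the submitters' processing notes. The processed signal in them is background-subtracted and spatially detrended within each array, per the file headers, and is not normalized between arrays. A value table deposited by the authors holds log2 values of the same arrays; how it was scaled is not given in the sources used here, apart from Partek, named without a version in the submitters' processing notes. Its columns had the same distribution, with a median of 3.89 on every array, as quantile normalization gives, and followed the scanner values of their own array in rank. Their scale and centring were read from the values only, and the table was used as an alternative.

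Each array had 62976 spots, of which 59305 were not controls, for 55681 distinct probes. Control spots and spots marked as outliers were left out, and spots of the same probe were averaged on the log2 scale; no probe was saturated on any array, and the 515 probes without a value on at least 1 array were left out of the tests. The share of probes well above background ran from 43.29% to 54.67% per array with a mean of 46.46%. Because that mean is under 50%, the log2 processed signal of each array was shifted by its 75th percentile over the 19863 probes well above background on all 12 arrays, in place of all probes. The number of arrays limits the precision of every value.

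Probes were named through the reference table by accession (27509 probes), by current symbol (3549) or by synonym (404), and 24219 kept the name in the file. A probe entered the tests if it was well above background on all 3 arrays of at least 1 group, and each gene was represented by its brightest such probe, which left 18545 genes. Of 229 named calls, 61 concerned a gene with 2 or more tested probes, and in 7 of these a probe had the opposite sign (Cd80 and Hspa4 and Ddx21 in 2 comparisons each, Pfkp in 1). Coordinates are those of the array design, on the mm9 build.

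Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, moderated test, two-sided) in 1 model of the 4 group means with 8 residual degrees of freedom, with Benjamini-Hochberg adjustment over the genes of each comparison and a threshold of 0.05. Input was read with jsonlite 2.0.0 and the package data.table, version 1.17.8. The 5 comparisons were KO against WT at 0 h, KO against WT at 3 h, 3 h against 0 h in WT, 3 h against 0 h in KO, and the difference between the activation effects (KO minus WT). Values are log2 differences ± the standard error from this model, with 3 arrays per group unless stated. Where no probe of a gene was well above background in the dimmer group, the fold is given as a lower bound: the mean of the brighter group over the dimmer group's mean of, per array, the higher of the probe's own value and the lowest value among probes well above background.

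The groups, comparisons, tests, named-gene rule and gene lists, and most alternatives, were fixed before the data were examined. The rule takes Cd83 first. In each comparison it then takes the 10 largest rises and 10 largest falls among genes with an adjusted p under the threshold, a gene symbol and no overlap between the arrays of both groups (5 and 5 for the difference of effects). From each list it takes up to 4 called members with the largest moderated statistic, or, where none was called, up to 2 members with the largest difference as values only. The 20 gene lists were Treg core signature, effector Treg, resting or naive Treg, T cell receptor (TCR) immediate early genes, NF-kB pathway and targets, helper T cytokines, inflammatory myeloid-type cytokines, chemokines, chemokine receptors and homing, costimulatory and inhibitory receptors, interferon response, ribosome biogenesis and MYC targets, cell cycle, glycolysis and hypoxia, sterol biosynthesis, cytokine receptor feedback, apoptosis regulators, heat shock proteins, unfolded protein and amino acid stress, and retinoid and TGF-beta response. Another 10 lists hold markers of T cells, CD8 T cells, B cells, plasma cells, monocytes and macrophages, dendritic cells, neutrophils, natural killer (NK) cells, erythroid cells and platelets. Lists with at least 3 tested members (29 of them) were tested with limma's camera at its preset inter-gene correlation of 0.01 and again with an estimated correlation, and with fry; the adjusted p of a list is Benjamini-Hochberg over the lists of a comparison.

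The scripts were tested on simulated data with 200 changed genes among 18545. Each gene was drawn independently of the others, with the same spread on all 12 arrays. For KO against WT at 0 h, 78% of genes changed by a log2 value of 2 and 30% of those changed by 1 were recovered; at 3 h the shares were 70% and 12%. For activation they were 64% and 20% in WT, 68% and 20% in KO, and for the difference of activation effects 50% and 0%. False calls numbered 3 of 100, 5 of 90, 7 of 96, 7 of 96 and 9 of 66 calls in the 5 comparisons, in that order.

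Alternatives were quantile normalization, no shift between arrays, normexp (offset 50) on the spot mean and background signals, the deposited log2 table, no filter on dim probes, only probes well above background on all 12 arrays, the mean of a gene's probes, eBayes with trend and robust estimation, array quality weights, an added 2-fold threshold, fits on only the groups compared, leaving out the 21-week arrays, age as a block in the KO activation effect, and leaving out each array in turn. A further 3 were added after seeing the data: the 75th percentile over all probes, the 21-week arrays left out together with an estimated correlation, and array weights from the gene-by-gene estimator, since the default estimator stopped without converging. KO and WT arrays share no slide, and a slide term would leave the KO activation effect as it stands because all KO arrays lie on 1 slide. No sample was left out of the main results.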

Results

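Transcripts of sorted splenic Treg were measured on 12 arrays, 3 each for WT at 0 h, WT at 3 h, KO at 0 h and KO at 3 h, where 3 h stands for stimulation through CD3 and CD28. P-values between time points treat the arrays as independent, though mice may be shared. Treg are CD4 T cells that restrain immune responses and depend on the transcription factor Foxp3; effector Treg are the antigen-experienced subset. The series asks what CD83, a surface protein of the immunoglobulin superfamily, contributes to these cells. The signal at the 75th percentile of all probes ran from 164.6 to 324 intensity units, and it was lowest on the 2 arrays from 21-week KO mice (180.9 at 0 h and 164.6 at 3 h). The first 3 principal components held 52.4%, 27.3% and 6.86% of the variance.

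The 2 arrays from 21-week KO mice stood apart from the rest. Relative to the WT mean at 0 h, the mean of 4 plasma cell markers was higher by 7.17 (log2) at 0 h and 7.66 at 3 h on these arrays, against -0.21 to 2.61 on the 4 arrays from 10-week KO mice. Over the same arrays the mean of 10 T cell markers was -1.90 and -3.04, against -0.95 to -0.30 on the 10-week KO arrays and -0.94 to -0.83 in WT at 3 h. The Treg core signature was -2.23 and -1.73 there, against -0.37 to 0.27 on the 10-week KO arrays. Both 21-week arrays deviated from the 10-week means of their time point in a similar way (Pearson r = 0.788 across 18545 genes, which are not independent replicates). Every KO value below includes these arrays unless it says otherwise.

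**Figure D1:**
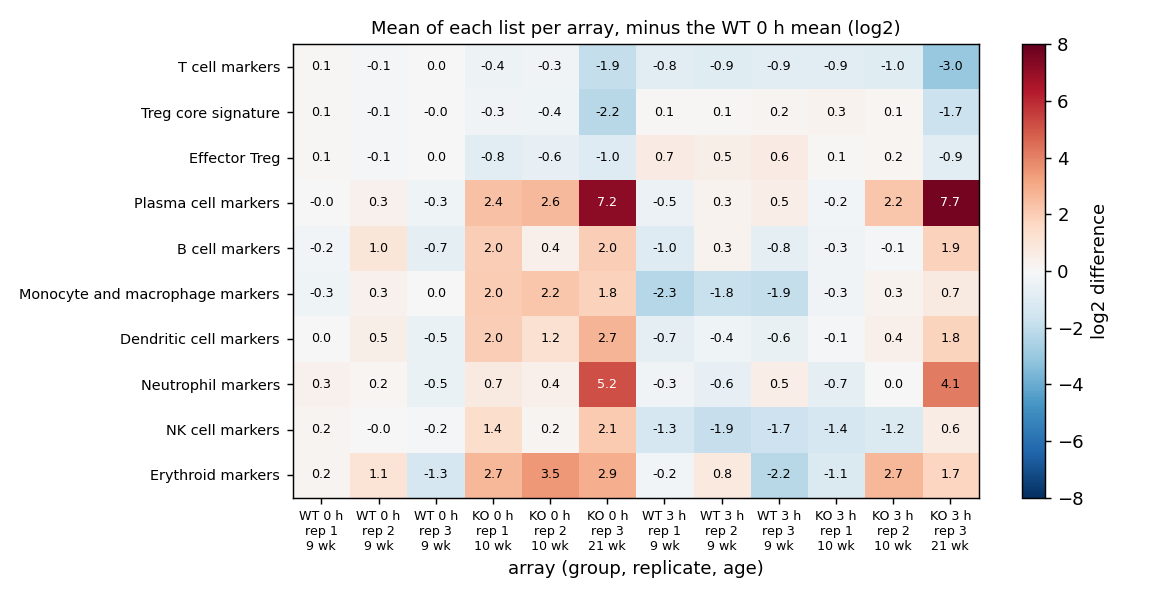
Mean of each marker or gene list on each array (columns: group, replicate, age in weeks), as a log2 difference from the mean of the 3 WT arrays at 0 h; colour and printed value show the same number. The 2 KO arrays from 21-week mice carry plasma cell marker means of 7.17 and 7.66, and monocyte and macrophage markers lie between 1.85 and 2.19 on the 3 KO arrays at 0 h.

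Cd83 was lower in every KO array than in every WT array of the same time point. At 0 h its normalized log2 signal was 0.75, 0.30 and 0.24 in KO and 2.36, 2.17 and 2.40 in WT. At 3 h it was 1.07, 1.07 and 1.93 in KO and 4.22, 3.70 and 3.66 in WT. The KO minus WT difference was -1.88 ± 0.265 at 0 h (limma adjusted p = 0.00887) and -2.50 ± 0.265 at 3 h (adjusted p = 0.00228). The signal was well above background on all 12 arrays, the KO ones included. Its probe lies on chromosome 13 from 43898276 to 43898335 (mm9). Which exon was deleted is not given in the sources used here, so the KO signal is not read as intact transcript.

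KO against WT at 0 h asks how non-activated Treg differ without CD83. Most genes that changed were higher in KO, among them many known from macrophages, while genes of effector Treg were among the falls. Klrg1, a lectin-like inhibitory receptor of terminally differentiated effector Treg, fell by 3.71 (log2; SE 0.742, adjusted p = 0.0331), and S100a4, a calcium-binding protein of antigen-experienced T cells, fell by 1.73 (SE 0.209, adjusted p = 0.00562). Fn1 (fibronectin) rose by 4.20 ± 0.652, Lyz2 (lysozyme of myeloid cells) by 4.08 ± 0.848, and Il1b (the inflammatory cytokine interleukin 1 beta) by 3.03 ± 0.450. In limma, 336 genes rose and 49 fell at an adjusted p under 0.05, of 18545 tested.

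Genes are named by rank of the fitted difference, which is not the order of the folds where a group is dim. Besides Fn1 and Lyz2, genes with a rise were Prss29, a serine protease (at least 7.68-fold, adjusted p = 0.00931), and Arhgef16, a guanine nucleotide exchange factor (at least 12.2-fold, 0.00325). Others were Nfasc, a cell adhesion protein of axons (at least 5.04-fold, 0.00701), Pdgfc, a growth factor (at least 4.27-fold, 0.0064), Nxpe5 (at least 5.59-fold, 0.000177) and Clec4d, a C-type lectin of myeloid cells (at least 7.19-fold, 0.0275). These 6 were not well above background in WT at 0 h. Fgf1, a fibroblast growth factor, rose by 3.86 ± 0.75 and Prom1, a membrane protein of progenitor cells, by 3.74 ± 0.764 (adjusted p = 0.0305 and 0.0365). Besides Klrg1, Cd83 and S100a4, genes with a fall were Frmd5 (at least 3.74-fold, adjusted p = 0.000493) and Morc1 (at least 1.56-fold, 0.0438, and 0.0611 without the 21-week arrays). Further falls were in Cep112, a centrosomal protein (-2.58 ± 0.433), Eps8l1, an actin regulator (-2.38 ± 0.464), Cc2d2a, a protein of the ciliary base (-2.37 ± 0.297), Smarcd3, a chromatin remodelling subunit (-2.05 ± 0.394), and Vegfc, a lymphatic growth factor (-1.77 ± 0.280), with adjusted p from 0.00597 to 0.0307. Cc2d2a turned to 0.987 (adjusted p = 0.701) with no filter on dim probes, where a brighter probe stood for the gene. Of the 28 named calls at 0 h, 24 held with quantile normalization, 20 with no shift between arrays and 18 with normexp. Array quality weights kept 7 with the default estimator, which did not converge, and 28 with the gene-by-gene one.

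Of 28 effector Treg genes, 2 fell (S100a4 and Klrg1), 1 rose (Pparg, a nuclear receptor of tissue Treg, by 1.29 ± 0.202) and 25 were not called. Adjusted over the list alone, 5 fell and 1 rose. The list was lower as a set (median -1.05, camera adjusted p = 0.000423), and fry gave an adjusted p of 0.0366. With an estimated correlation the adjusted p was 0.253. Without the 21-week arrays 12 members fell and 2 rose, among them Il1rl1, the receptor of interleukin 33 (-1.26), Tnfrsf4, the costimulatory receptor OX40 (-1.09), and Icos (-0.78), chosen after their values were seen. The list median was then -0.89 (camera adjusted p = 4e-08, and 0.229 with an estimated correlation). T cell markers moved the same way. None of the 10 was called and all were below 0, with a median of -0.85 over 12 arrays (adjusted p = 0.00341, and 0.463 with an estimated correlation) and -0.40 without the 21-week arrays, where 3 fell. With fry the adjusted p of these markers was 0.258 over 12 arrays and 0.00515 without the 21-week arrays.

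None of the 20 Treg core genes was called over all genes, and 1 rose adjusted over the list alone. The list was lower as a set (median -1.17, adjusted p = 0.00258, and 0.427 with an estimated correlation), and without the 21-week arrays its median was -0.37 (adjusted p = 0.000142, and 0.229 with an estimated correlation), where 1 member rose and 5 fell. Itgae, an integrin of tissue Treg, was at -2.39 ± 1.04 (adjusted p = 0.308). Foxp3 went the other way: its single probe (chromosome X, 7172301 to 7172360, mm9) was well above background on 6 of 6 KO arrays and on 0 of 6 WT arrays, although all samples were sorted as Treg. The KO minus WT difference at 0 h was at least 5.82-fold with an adjusted p of 0.0503, and at least 2.72-fold (adjusted p = 0.0141) without the 21-week arrays. The sources used here do not say whether the KO mice carry a changed Foxp3 allele, so the KO signal is not read as more intact transcript. Of the resting or naive Treg genes none of 20 was called (median -0.54, adjusted p = 0.0666, and -0.01 without the 21-week arrays), with Id3 at -1.02 ± 0.574 (adjusted p = 0.435).

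Markers of several other cell types were higher in KO at 0 h. The examples given for them were chosen after their values were seen. Of 12 monocyte and macrophage markers 9 rose and none fell, or 11 adjusted over the list alone (median 2.07, camera adjusted p = 1.23e-12, fry adjusted p = 0.00267, and 0.253 for camera with an estimated correlation). Csf1r, the receptor of the macrophage growth factor, rose by 2.18 ± 0.315 and C1qb, a complement component made by macrophages, by 2.17 ± 0.322 (adjusted p = 0.00931 and 0.0102). Leaving out the 21-week arrays, 10 of the 12 rose, with a median of 2.23. Of 10 dendritic cell markers 1 rose, the integrin Itgax (3.11 ± 0.439, adjusted p = 0.00902), or 8 adjusted over the list alone (median 1.94, adjusted p = 9.51e-06, and 0.253 with an estimated correlation). All 8 erythroid markers were above 0 but none was called (8 adjusted over the list alone, median 2.96, adjusted p = 3.17e-05, and 0.427 with an estimated correlation). The 8 became 0 without the 21-week arrays (median 3.05, adjusted p = 0.00611, and 0.484 with an estimated correlation). Of 8 NK cell markers 1 rose, Tyrobp, an adaptor that myeloid cells share (2.19 ± 0.384, list median 1.15, adjusted p = 0.00258, and 0.427 with an estimated correlation). None of 10 B cell markers (median 1.41, adjusted p = 0.00197), 4 plasma cell markers (4.10, 0.0114) and 3 platelet markers (2.92, 0.00654) was called, but adjusted over the list alone all 3 platelet markers rose. Under an estimated correlation the adjusted p was 0.427, 0.427 and 0.293. The platelet call was lost without the 21-week arrays (2.19, 0.0593), and the plasma cell and NK medians were then 2.65 and 0.73 (adjusted p = 0.0118 and 0.0328, or 0.364 and 0.46 with an estimated correlation). Neither were the 4 neutrophil markers called (2.59, 0.368, and 0.25 without the 21-week arrays) or the 2 CD8 T cell markers tested (1.30, too few for a list test; 2 rose adjusted over the list alone).

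Some inflammatory and stress genes were called as well. Besides Il1b, Ccl2, a chemokine that draws monocytes, rose (at least 1.22-fold, adjusted p = 0.0062), as did Ier3, an immediate early gene (2.09 ± 0.356, adjusted p = 0.0187), and Atf3, a stress-induced transcription factor (at least 4.64-fold, adjusted p = 0.0198). These were the called members of 4 inflammatory myeloid-type cytokines (median 1.11, adjusted p = 0.00825, 2 rises adjusted over the list alone), 11 chemokines (median 1.29, adjusted p = 0.00508, 4 rises adjusted over the list alone), 23 TCR immediate early genes (median -0.22, adjusted p = 0.916) and 16 genes of unfolded protein and amino acid stress (median 1.03, adjusted p = 0.00428). With an estimated correlation the adjusted p of the cytokines, chemokines and stress genes was 0.253, 0.446 and 0.463. The stress list was at 0.29 without the 21-week arrays (adjusted p = 0.0193, and 0.477 with an estimated correlation). Of 20 cell cycle genes 1 rose, the replication licensing factor Mcm2 (0.92 ± 0.161, adjusted p = 0.0205), or 8 adjusted over the list alone (median 1.18, adjusted p = 9.78e-09, 0.427 with an estimated correlation and 0.0975 with fry). The 8 became 1 without the 21-week arrays (median 0.851, camera adjusted p = 0.000132, and 0.484 with an estimated correlation). Bcl2l1, an anti-apoptotic gene, fell by 0.98 (SE 0.152, adjusted p = 0.0121) as the only called member of 17 apoptosis regulators (median -0.25, adjusted p = 0.0221, and 0.253 with an estimated correlation). Cd80, a ligand of CD28, rose by 1.01 ± 0.187 (adjusted p = 0.0249), but its other probe gave -0.63; it was the only member called of 21 costimulatory and inhibitory receptors (median -0.46, adjusted p = 0.109; 1 rise and 1 fall adjusted over the list alone).

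The remaining lists held no called gene at 0 h, or 3 falls among the homing genes adjusted over the list alone. As sets, the 28 interferon response genes (median -0.54, adjusted p = 0.00027), 19 sterol biosynthesis genes (-0.36, 0.00453), 12 genes of the retinoid and TGF-beta response (-0.59, 0.00258), 19 NF-kB genes (-0.35, 0.0221) and 14 chemokine receptor and homing genes (-0.42, 0.0233) were lower in KO. Under an estimated correlation their adjusted p was 0.427, 0.463, 0.427, 0.508 and 0.427, and with fry it was 0.201, 0.28, 0.188, 0.371 and 0.175. The NF-kB and homing calls were lost without the 21-week arrays (-0.17 and -0.10, adjusted p = 0.34 and 0.0605). The interferon and retinoid lists were then at -0.17 and -0.25 (0.0237 and 0.0322, or 0.663 and 0.384 with an estimated correlation). Helper T cytokines (median -0.29 but mean 0.43 and an upward test, adjusted p = 0.922), ribosome biogenesis and MYC targets (0.13, 0.0721), glycolysis and hypoxia (-0.19, 0.233), cytokine receptor feedback (-0.49, 0.0551) and heat shock proteins (0.04, 0.105) were not called as sets, though glycolysis was without the 21-week arrays (-0.16, 0.0475, or 0.229 with an estimated correlation).

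KO arrays did not overlap with WT arrays in 31.7% of genes at 0 h, where chance gives 10%. All KO arrays lay on 1 slide and the WT arrays on others, so genotype and slide cannot be told apart for any gene here. Without the 21-week arrays 875 genes rose and 363 fell (373 of the 385 calls were shared); leaving out WT replicate 1 or 3 left 83 or 86 calls and KO replicate 1, 2 or 3 left 204, 187 or 214.

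**Figure D2:**
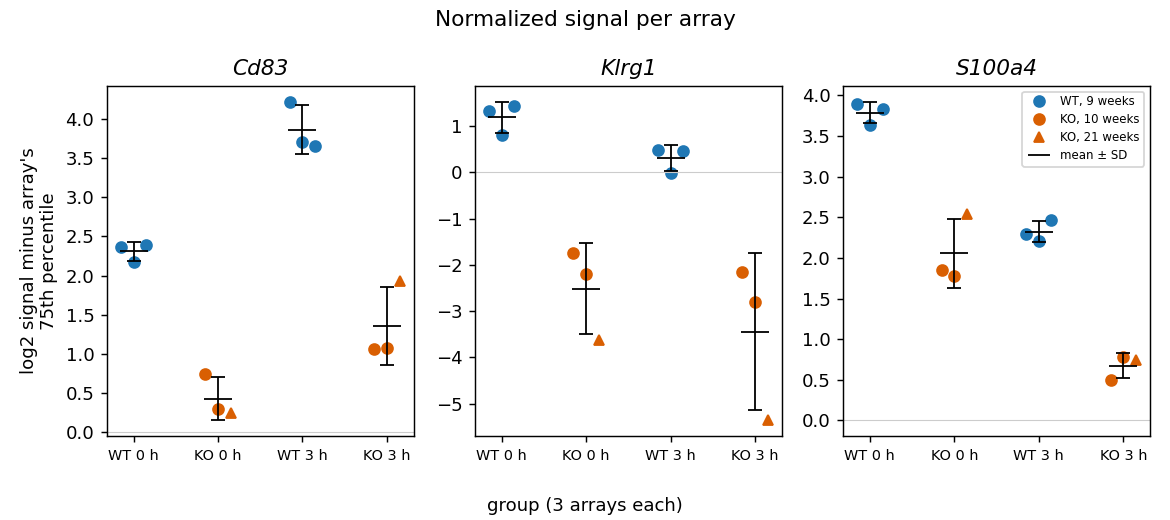
Normalized log2 signal of Cd83, Klrg1 and S100a4 on each of the 12 arrays by group, with mean ± SD over 3 arrays; triangles mark the 21-week KO arrays. KO arrays lie below the WT arrays of the same time point for all 3 genes, for example -3.63 to -1.75 against 0.80 to 1.43 for Klrg1 at 0 h.

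KO against WT at 3 h asks the same of activated Treg. The pattern of 0 h was seen again: more genes rose than fell, macrophage genes were prominent among the rises, and Klrg1 (-3.75 ± 0.742, adjusted p = 0.0383), S100a4 (-1.65 ± 0.209, adjusted p = 0.00464) and Cd83 were among the falls. Foxp3 was among the rises, at least 8.9-fold (adjusted p = 0.02), and at least 5.86-fold without the 21-week arrays (0.00552). In limma 233 genes rose and 35 fell. The lowest signal well above background was higher on the KO arrays at 3 h (-6.84, -6.74 and -6.12) than on the WT arrays (-7.65, -7.39 and -7.50), so dim probes lean towards a rise. With no filter on dim probes 4924 genes rose and 115 fell. With only probes well above background on all 12 arrays, 141 rose and 18 fell. Fold changes at 3 h and 0 h, which rest on different arrays, correlated with r = 0.796 across genes, or 0.639 without the 21-week arrays. The 2 comparisons are not independent, since mice may be shared and all KO arrays lie on 1 slide. In both, 164 genes rose and 18 fell, where independent lists would share 4.22 and 0.0925.

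Other rises at 3 h were Clec4b1, a C-type lectin of myeloid cells (at least 7.41-fold, adjusted p = 0.00466), Arhgef16 (at least 10.8-fold, 0.00228), Kif1a, a kinesin motor (at least 4.16-fold, 0.0149), and Fpr2, a formyl peptide receptor (at least 3.06-fold, 0.00173). Also higher were Fgf1 (3.88 ± 0.75), Mmp19, a matrix protease (3.82 ± 0.301), Slamf8, a receptor of macrophages (3.73 ± 0.717), Marco, a macrophage scavenger receptor (3.70 ± 0.662), and Tns3, an adhesion protein (3.64 ± 0.703), with adjusted p from 0.00173 to 0.0352. Other falls were Muc4 and Tff1, known from mucosal secretions (-2.85 ± 0.580 and -2.74 ± 0.435), Smarcd3 (-2.56 ± 0.394), Eps8l1 (-2.55 ± 0.464), C1qtnf6 (-2.16 ± 0.384) and Dscam, a neuronal adhesion molecule (-2.15 ± 0.420), with adjusted p from 0.0109 to 0.0441. Cga, a hormone subunit, and Frmd5 fell at least 2.47-fold and 1.46-fold (adjusted p = 0.00521 and 0.00253). Calls lost without the 21-week arrays were Fgf1 (adjusted p = 0.06), Marco (0.0578), Tff1 (0.0525) and Dscam (0.0735). All 26 named calls at 3 h held with the mean of a gene's probes. Of the 26, 19 held with the deposited log2 table, 18 with quantile normalization, 15 with no shift and 9 with normexp. Only 9 could be tested on probes well above background on all 12 arrays, and these 9 held.

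Of 28 effector Treg genes 2 fell and 1 rose (Pparg, 1.25 ± 0.202), or 5 and 1 adjusted over the list alone (median -1.16, camera adjusted p = 5.93e-05, fry 0.0416, and 0.151 for camera with an estimated correlation). Leaving out the 21-week arrays, 7 fell and 1 rose, with a median of -0.39 (adjusted p = 1.36e-09, and 0.109 with an estimated correlation), while T cell markers then had a median of -0.07 (adjusted p = 0.311). Over 12 arrays T cell markers were lower as a set with no gene called (median -0.75, adjusted p = 0.00449, and 0.552 with an estimated correlation). Treg core genes other than Foxp3 were not called (list median -1.06, adjusted p = 0.0174, and 0.552 with an estimated correlation; median -0.09 without the 21-week arrays). None of the resting or naive Treg genes was called (median -0.40, adjusted p = 0.0687; 0.24 without the 21-week arrays, adjusted p = 0.0277, and 0.710 with an estimated correlation).

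Monocyte and macrophage markers rose in 9 of 12 cases at 3 h, or 11 adjusted over the list alone (median 2.34, adjusted p = 5.74e-17, and 0.106 with an estimated correlation), for example Csf1r (2.73 ± 0.315) and Vcam1, an adhesion molecule of splenic macrophages (2.95 ± 0.409), chosen after their values were seen. Without the 21-week arrays 8 rose. Il1b (2.78 ± 0.450, adjusted p = 0.0146), Il18, another inflammatory cytokine (2.60 ± 0.480, 0.028), Ccl2 (2.08 ± 0.233, 0.00258) and Il4, the type 2 helper cytokine (2.28 ± 0.448, 0.0377), also rose, but Il4 was not called without the 21-week arrays (1.94, adjusted p = 0.108). The inflammatory cytokines (2 of 4 called, median 1.59, adjusted p = 0.00205) and chemokines (1 of 11, or 4 adjusted over the list alone, 2.08, 5.18e-06) were higher as sets. With an estimated correlation their adjusted p was 0.106 and 0.371. The chemokine median was 1.11 without the 21-week arrays (adjusted p = 0.000523, and 0.109 with an estimated correlation). Helper T cytokines were not called as a set (0.85, 0.0692). Dendritic (median 1.21, adjusted p = 0.00783), NK (0.79, 0.0189), erythroid (1.62, 0.0189) and B cell markers (0.90, 0.0376) were higher as sets, with 1, 1, 0 and 0 genes called, or 2, 1, 0 and 0 adjusted over the list alone. Under an estimated correlation the adjusted p was 0.552, 0.552, 0.552 and 0.566. All 4 calls were lost without the 21-week arrays (0.53, 0.19, 1.38 and 0.33, adjusted p = 0.0802, 0.481, 0.238 and 0.596).

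No gene of the other lists was called at 3 h. TCR immediate early genes (median -0.50, adjusted p = 0.0335) and NF-kB genes (-0.41, 0.00463) were lower as sets, with an adjusted p of 0.566 and 0.552 with an estimated correlation. Both calls were lost without the 21-week arrays, with the TCR list at 0.13 (adjusted p = 0.55) and NF-kB at -0.02 (0.415). Cytokine receptor feedback (-0.69, 0.00456), chemokine receptors and homing (-0.46, 0.00463), costimulatory receptors (-0.49, 0.0376), apoptosis regulators (-0.21, 0.00974) and glycolysis (-0.12, 0.0376) were lower as sets, with 3 homing genes falling adjusted over the list alone. With an estimated correlation their adjusted p was 0.552, 0.385, 0.552, 0.151 and 0.220. The feedback and costimulatory calls were lost without the 21-week arrays (-0.04 and -0.01, adjusted p = 0.38 and 0.968), and the homing list was at -0.10 (0.0182, and 0.319 with an estimated correlation). Cell cycle (0.77, 0.0135) and unfolded protein stress genes (0.76, 0.0196) were higher, with 0.585 and 0.566 under an estimated correlation, and both calls were lost without the 21-week arrays (0.32 and 0.17, adjusted p = 0.391 and 0.311). Plasma cell (2.86, 0.0542; 0.92 without the 21-week arrays), neutrophil (1.54, 0.638; then 0.05), platelet (1.29, 0.0868), interferon (0.19, 0.435), ribosome biogenesis (-0.07, 0.276), sterol (0.15, 0.175), heat shock (-0.14, 0.104) and retinoid and TGF-beta genes (-0.50, 0.127) were not called as sets. Sterol genes were called without the 21-week arrays (0.41, adjusted p = 0.000523, and 0.718 with an estimated correlation). The 2 CD8 T cell markers were not called (median 0.80).

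KO and WT arrays did not overlap in 19.2% of genes at 3 h, where chance gives 10%. Fitted on these 6 arrays alone, limma called 0 genes, none of the 26 named calls among them, so the 268 calls rest on the spread shared with the other groups. In the 12-array model 1957 genes had an unadjusted p under 0.05. Leaving out WT replicate 1 or 3 gave 130 or 137 calls and leaving out KO replicate 1 gave 557, while 209 of the 268 calls were shared without the 21-week arrays (372 calls).

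Activation of WT Treg compares cells after 3 h with antibodies to CD3 and CD28 with cells at 0 h. No group was kept for 3 h without the antibodies. Stimulation and time in culture therefore cannot be told apart in either genotype, and activation stands for both. The response was large: 2466 genes rose and 3085 fell in limma. Transcription factors of the immediate TCR response were among the rises, while interferon-induced genes and macrophage markers fell. Atf3 rose at least 281-fold (adjusted p = 1.85e-05), Fosl2, a subunit of AP-1, by 6.67 ± 0.668 (log2), and the nuclear receptors Nr4a2 and Nr4a3 by 6.43 ± 0.746 and 6.05 ± 0.855. The interferon-induced gene Ifit3 fell by 4.23 (SE 0.542, adjusted p = 0.000612).

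Other rises in WT were Gls2, a glutaminase (at least 223-fold, adjusted p = 0.000292), Calca, which encodes calcitonin gene-related peptide (at least 77.3-fold, 0.000246), and Ramp3, a receptor activity-modifying protein (7.71 ± 0.757). Further rises were in Fndc4 (at least 34.9-fold), the transcription factors Evx1 (at least 37.3-fold) and Scrt1 (at least 35.8-fold), and Crem, a factor of the cyclic AMP response (6.11 ± 0.488, adjusted p = 9.28e-05). Genes with a fall were the tissue kallikreins Klk1 (at least 8.28-fold, adjusted p = 0.00295) and Klk1b5 (-4.67 ± 0.975), which belong to a family of near-identical genes. Lower too were Itih5 (-4.86 ± 0.710), Ifit3b (-4.70 ± 0.559), P2ry13, a nucleotide receptor (at least 5.23-fold), Drc1 (-4.61 ± 1.09), Cep112 (at least 7.88-fold), Tmem273 (-4.49 ± 0.366), Khdc1a (at least 12.5-fold) and Tcstv3 (-4.43 ± 0.410), with adjusted p from 3.97e-05 to 0.0109.

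Of 23 TCR immediate early genes 15 rose and none fell, or 16 adjusted over the list alone, and all 23 were above 0 (median 1.98, camera adjusted p = 2.86e-08, fry 0.00357, and 0.408 for camera with an estimated correlation); Fosb rose by 4.86 ± 0.693. Of 19 NF-kB genes 11 rose and none fell (11 adjusted over the list alone; median 1.27, adjusted p = 1.6e-05, and 0.567 with an estimated correlation), for example Tnfaip3, a feedback inhibitor (4.74 ± 0.835), and Nfkb2 (2.15 ± 0.309). Of 16 cytokine receptor feedback genes 6 rose and 1 fell, or 8 and 1 adjusted over the list alone (median 1.52, adjusted p = 0.00775, and 0.884 with an estimated correlation), with the kinase Pim3 at 2.51 ± 0.393 and Stat3 at 1.99 ± 0.243. Of 13 heat shock proteins 8 rose and 1 fell, or 9 and 1 adjusted over the list alone (median 0.79, adjusted p = 0.00053, and 0.408 with an estimated correlation), led by Hspa1a (6.06 ± 0.714). Of 16 genes of unfolded protein and amino acid stress 7 rose and 1 fell (the same adjusted over the list alone; median 1.05, adjusted p = 0.00506, and 0.884 with an estimated correlation), including Hspa5, an endoplasmic chaperone (1.75 ± 0.445). Of 17 apoptosis regulators 8 rose and 4 fell (the same adjusted over the list alone; median 0.29, adjusted p = 0.0803): the pro-apoptotic Bcl2l11 and Pmaip1 rose by 3.17 ± 0.230 and 2.94 ± 0.290, and Tnfsf10, the death ligand TRAIL, fell by 2.48 (SE 0.370).

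Treg genes moved in both directions. In the core signature 3 rose and 3 fell of 20 (the same adjusted over the list alone; median -0.08, mean 0.14, adjusted p = 0.824): the zinc finger gene Plagl1 by 5.13 ± 0.814, the inhibitory receptor Ctla4 by 2.28 ± 0.666, and Nrp1, a receptor of thymic Treg, by -1.67 ± 0.513. Of the effector Treg genes 8 rose and 4 fell (9 and 5 adjusted over the list alone; median 0.22, adjusted p = 0.302). Il10, a suppressive cytokine, rose by 3.01 ± 0.294 and Id2, a transcriptional regulator, by 1.35 ± 0.267, while S100a4 fell by 1.47 (SE 0.209). Of the resting or naive genes 1 rose and 4 fell (the same adjusted over the list alone; median 0.07, mean -0.25, adjusted p = 0.905), among them Dapl1 (-3.13 ± 0.440) and Bcl2 (-1.76 ± 0.362). Chemokine receptors and homing genes had 3 rises and 6 falls (3 and 7 adjusted over the list alone; median -0.60, adjusted p = 0.377): Cxcr4 rose by 3.42 ± 0.331, and Cxcr5, which guides cells to B cell follicles, fell by 2.05 (SE 0.213). Among costimulatory receptors 5 rose and 3 fell (the same adjusted over the list alone; median 0.20, adjusted p = 0.426), with Tnfsf4, the ligand of OX40, up at least 8.87-fold and Tnfsf14 at -4.06 ± 0.724.

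Of 28 interferon response genes none rose and 15 fell, or 18 adjusted over the list alone (median -1.65, adjusted p = 1.6e-05, and 0.654 with an estimated correlation), with the antiviral genes Oas3 at -3.14 ± 0.383 and Mx1 at -3.08 ± 0.382. Helper T cytokines had 4 falls and no rise (1 rise and 5 falls adjusted over the list alone; median -0.91, adjusted p = 0.377), for example Il4 (-2.32 ± 0.448) and Il21 (at least 2.51-fold lower). The inflammatory cytokines had 1 rise (Il1b, 1.78 ± 0.450) and 1 fall (Il18, -2.02 ± 0.480), with a list median of 0.12 (adjusted p = 0.905). So did the chemokines, with Ccl2 (at least 1.08-fold higher) and Ccl1 (-3.94 ± 0.871); their median was -0.12 where the list test pointed up (adjusted p = 0.953). Ribosome biogenesis and MYC targets had 7 rises and 3 falls (8 and 3 adjusted over the list alone; median 0.06, adjusted p = 0.163), with Odc1, the first enzyme of polyamine synthesis, at 3.53 ± 0.208. Glycolysis genes had 5 rises and 1 fall (median 0.31, adjusted p = 0.0803), with Slc16a3, a lactate exporter, at 3.86 ± 0.811. Sterol genes had 3 rises and 4 falls (median 0.16, adjusted p = 0.377), with Insig1 at 1.81 ± 0.284 and Mvd at -1.48 ± 0.231. Retinoid and TGF-beta genes had 3 rises and 2 falls (median 0.11, adjusted p = 0.366), with Tgif1 at 3.21 ± 0.549. None of 20 cell cycle genes was called (median -0.63, adjusted p = 0.391).

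Of the marker lists for other cells, 2 were lower as sets after activation in WT. Of 12 monocyte and macrophage markers 9 fell, or 10 adjusted over the list alone (median -2.31, adjusted p = 2.24e-05, and 0.408 with an estimated correlation). NK cell markers had 4 falls of 8 (median -1.29, adjusted p = 0.0448, and 0.884 with an estimated correlation) and T cell markers 2 of 10 (median -0.95, adjusted p = 0.189). B cell (2 falls, median -0.50, adjusted p = 0.681) and dendritic cell markers (1 rise and 2 falls, or 1 and 3 adjusted over the list alone, -0.52, 0.681) were not called as sets. Nor were plasma cell (0.15, 0.905), neutrophil (-0.16 with an upward test, 0.920), erythroid (-0.44, 0.905) and platelet markers (-0.45, 0.930), which held no called gene. Of 2 CD8 T cell markers 1 fell, or 2 adjusted over the list alone.

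The 3 h and 0 h arrays of WT did not overlap in 68.5% of genes, where chance gives 10%. They lay on a slide each. The slide alone would not give the match with KO, whose arrays of both times lie on 1 slide (r = 0.845, with 1171 rises and 1587 falls in both, where independent lists would share 181 and 305). Time in culture was shared by both genotypes, so the match does not separate it from stimulation. For the other WT calls activation and slide cannot be told apart. The count was 2822 with no shift between arrays, 3441 with an added 2-fold threshold and 10353 without the 21-week KO arrays, which enter only through the shared spread; all 5551 calls were shared in the last. There the glycolysis and T cell lists were called too (adjusted p = 0.0401 and 0.00258, or 0.249 and 0.41 with an estimated correlation).

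Activation of KO Treg was measured on arrays of 1 slide. In limma 1364 genes rose and 1833 fell, with transcription factors of the TCR response among the rises. The balance depended on scaling: 268 rose and 2193 fell with no shift between arrays, and 1623 rose and 1379 fell with normexp. Ramp3 rose by 6.77 ± 0.757 (adjusted p = 0.000768), Nr4a3 by 6.14 ± 0.855, Atf3 by 5.75 ± 0.470 and Il10 by 4.19 ± 0.294 (8.23e-05). Cd83 itself rose by 1.55 ± 0.265 in WT (adjusted p = 0.00248) and by 0.92 ± 0.265 in KO (0.0392), and by 0.55 in KO without the 21-week arrays (0.0742).

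Further rises in KO were Calca (at least 22.1-fold), Maff, a small MAF factor (5.78 ± 0.437), Nr4a2 (5.60 ± 0.746), the matrix proteases Mmp10 (at least 11.9-fold) and Mmp19 (at least 12.6-fold), Crem (5.37 ± 0.488) and the neuropeptide gene Npy (at least 7.3-fold), with adjusted p from 7.45e-05 to 0.00172. Several falls were in genes of other cells: Cd209a and Clec10a, lectins of dendritic cells and macrophages (at least 4.47-fold, and -3.82 ± 0.835), Fcgr1, an antibody receptor of macrophages (-3.91 ± 0.715), and Klrb1c and Klra2, receptors of NK cells (at least 6.01-fold, and -3.69 ± 0.634). The others were Klk1b5 (-4.51 ± 0.975), Klk1 (-4.33 ± 0.870), Klk1b26 (-4.15 ± 0.805), Ifitm6 (-4.48 ± 0.936) and P2ry13 (-3.98 ± 0.302). Adjusted p for these falls ran from 0.000118 to 0.0133.

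TCR immediate early genes rose in 10 of 23 cases with no fall, or 13 adjusted over the list alone (median 1.31, adjusted p = 1.63e-07, and 0.476 with an estimated correlation), for example Fosl1 (at least 5.26-fold) and Fosl2 (4.88 ± 0.668). NF-kB genes rose in 9 of 19 cases (9 adjusted over the list alone; median 1.23, adjusted p = 5.28e-07, and 0.476 with an estimated correlation), for example Nfkb2 (1.83 ± 0.309). Cytokine receptor feedback (3 rises of 16, median 1.23, adjusted p = 0.00502), heat shock proteins (5 of 13, 0.57, 0.00814), unfolded protein and amino acid stress (5 of 16, 1.02, 0.00284) and retinoid and TGF-beta genes (3 of 12, 0.62, 0.0230) were higher as sets with no gene falling. Adjusted over the list alone the rises were 3, 5, 5 and 4, with 1 heat shock gene falling. Under an estimated correlation their adjusted p was 0.684, 0.592, 0.684 and 0.684. Sterol biosynthesis genes, the enzymes of cholesterol synthesis, rose in 8 of 19 cases and fell in 1, or 12 and 3 adjusted over the list alone (median 0.94, adjusted p = 0.000739, and 0.684 with an estimated correlation), for example Insig1 (2.09 ± 0.284). Apoptosis regulators had 7 rises and 2 falls (8 and 3 adjusted over the list alone; median 0.35, adjusted p = 0.0205, and 0.476 with an estimated correlation), with Bcl2l11 at 2.69 ± 0.230 and Bcl2l1 at 1.21 ± 0.152. The apoptosis call was lost without the 21-week arrays (0.63, adjusted p = 0.0773).

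Interferon response genes fell in 9 of 28 cases (9 adjusted over the list alone, with 2 rises; median -1.14, adjusted p = 0.00814, and 0.684 with an estimated correlation), for example Ifit3 (-2.83 ± 0.542). Cell cycle genes fell in 3 of 20 cases, or 4 adjusted over the list alone (median -1.19, adjusted p = 0.000408, and 0.684 with an estimated correlation), among them Mcm2 (-0.89 ± 0.161). Chemokines had 3 rises (Ccl2, Ccl4 and Cxcl10; 3 rises and 1 fall adjusted over the list alone, median 0.14, adjusted p = 0.272). Without the 21-week arrays 3 chemokines rose and 4 fell (median -0.66, adjusted p = 0.896). Effector Treg genes had 3 rises and 2 falls (median 0.31, adjusted p = 0.255), Treg core genes 3 rises (0.53, 0.272), and resting or naive genes 1 rise and 2 falls (-0.24, 0.735; 1 and 1 adjusted over the list alone). Chemokine receptors had 1 rise and 5 falls (-0.66, 0.0872) and costimulatory receptors 3 rises and 2 falls (0.17, 0.313; 7 and 3 adjusted over the list alone). Helper T cytokines (1 fall, or 2 adjusted over the list alone, median -0.07, adjusted p = 0.735), inflammatory cytokines (1 rise, 0.23, 0.556), ribosome biogenesis (2 rises and 2 falls, -0.05 but mean 0.08 and an upward test, 0.684) and glycolysis (2 rises and 1 fall, 0.25, 0.0861) were not called as sets. Effector Treg, glycolysis and T cell lists were called without the 21-week arrays (0.54, 0.21 and -0.51, adjusted p = 0.0313, 0.0155 and 0.0156, and 0.498, 0.173 and 0.462 with an estimated correlation).

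Monocyte and macrophage markers fell in 8 of 12 cases, or 10 adjusted over the list alone (median -2.06, adjusted p = 9.5e-06, and 0.476 with an estimated correlation). NK cell markers fell in 3 of 8, or 5 adjusted over the list alone (median -1.92, adjusted p = 0.00284, and 0.684 with an estimated correlation). T cell (1 fall, median -0.77, adjusted p = 0.0879), B cell (2 falls, -0.82, 0.0912) and dendritic cell markers (1 rise and 2 falls, or 1 and 3 adjusted over the list alone, -1.28, 0.0879) were not called as sets. Neither were erythroid (-1.95, 0.0599), plasma cell (-0.70, 0.794), neutrophil (-1.05, 0.857) and platelet markers (-1.32, 0.283), without a called gene. Of 2 CD8 T cell markers 1 fell, or 2 adjusted over the list alone.

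The KO arrays of 3 h and 0 h did not overlap in 24.4% of genes, where chance gives 10%. The count moved from 105 with the 6 KO arrays fitted alone, where 12 of the 85 named calls held, to 8570 without the 21-week arrays (3133 of 3197 calls shared). Most of the 3197 calls thus rest on the spread shared with the WT groups, whose arrays lay closer together than the KO arrays. With age as a block it was 7146, leaving out KO replicate 3 at 3 h gave 6912, and leaving out KO replicate 2 at 0 h, or replicate 1 or 2 at 3 h, gave 1803, 1886 or 1836.

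The difference of activation effects asks whether the change from 0 h to 3 h differs between KO and WT. No single gene passed the test of limma. An unadjusted limma p under 0.05 was found for 691 of 18545 genes, fewer than that threshold gives by chance when no gene differs. Values among the listed genes were for example Ccl1, a chemokine (4.82 ± 1.23, adjusted p = 1), which was at -3.94 in WT, and the AP-1 subunits Fos and Fosb (-2.89 ± 1.10 and -2.86 ± 0.980, adjusted p = 1). Cd83 was at -0.62 ± 0.375 (adjusted p = 1). Effects in WT and KO, which rest on different arrays, correlated with r = 0.845 across genes, or 0.859 without the 21-week arrays. In both genotypes 1171 genes rose and 1587 fell, where independent lists would share 181 and 305, and 1 gene moved in opposite directions.

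**Figure D3:**
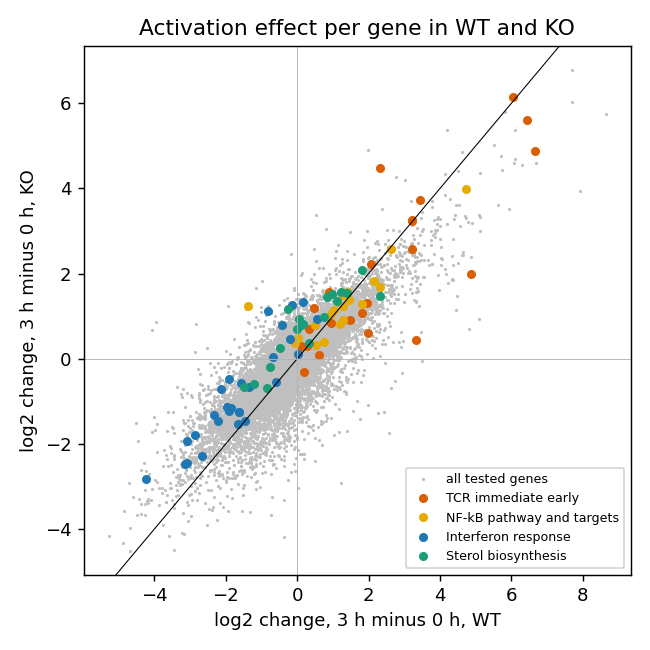
Log2 change from 0 h to 3 h of each of 18545 tested genes (grey) in WT (x axis) and KO (y axis), with members of 4 lists in colour and the line of equal effects. Effects correlate with r = 0.845 across genes; interferon response and sterol biosynthesis genes lie mostly above the line, with median differences of 0.70 and 0.58.

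As sets, interferon response genes (28 of 28 above 0, median 0.70, camera adjusted p = 3.8e-06) and sterol biosynthesis genes (18 of 19 above 0, 0.58, 4.21e-05) had higher activation effects in KO, that is, a smaller fall and a larger rise. Cell cycle (-0.57, 4.21e-05), heat shock (-0.24, 0.00231) and ribosome biogenesis genes (-0.18, 0.00842), and erythroid (-1.32, 0.0148) and dendritic cell markers (-0.72, 0.0257), had lower ones. With an estimated correlation the adjusted p of these 7 lists ran from 0.874 to 0.880, and with fry it was 0.959 for each. Adjusted over the list alone 1 chemokine was higher and 1 gene each of the costimulatory, stress and dendritic cell lists was lower. No other list was called as a set: TCR immediate early genes had a median of -0.13 (adjusted p = 0.0653), NF-kB genes -0.05 (0.663; mean 0.04), effector Treg genes -0.05 (0.843; mean 0.02) and monocyte and macrophage markers 0.44 (0.185; 0.06 without the 21-week arrays). Without the 21-week arrays the medians of the interferon, sterol and cell cycle genes were 0.24, 0.69 and -0.53 (adjusted p = 0.0272, 7.19e-07 and 0.00155, and 0.732 for each with an estimated correlation). Dendritic cell markers were then at -1.04 (0.0219), and the heat shock, ribosome and erythroid calls were lost (-0.05, -0.08 and -1.76, adjusted p = 0.277, 0.197 and 0.0601). Treg core and T cell lists were called there (0.28 and 0.39, each 0.00197), as were resting or naive (0.23, 0.0359), retinoid (0.29, 0.0329) and plasma cell genes (-1.64, 0.0481). The adjusted p of each was 0.732 with an estimated correlation. The comparison mixes slides, since KO activation lies within 1 slide and WT activation spans 2. The simulation, with equal spread on all arrays and independent genes, recovered 0% of genes with a difference of 1 and 50% of those with 2.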

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

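The tests of the first 3 patterns in this part were chosen after the result was seen; the list tests of the difference of activation effects were planned.

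On the 2 KO arrays from 21-week mice, plasma cell markers lay 5.54 (log2, median) above those on the 4 arrays from 10-week KO mice, and T cell markers lay at -1.69 and Treg core genes at -2.39. Neutrophil markers were higher too (4.94, camera adjusted p = 0.0133, and 0.295 with an estimated correlation), as were NK (1.59, 0.00313), dendritic (1.27, 0.00889) and B cell markers (0.793, 0.022). With an estimated correlation the NK, dendritic and B cell lists had 0.414, 0.402 and 0.616, and the plasma cell list 0.406. Called over all genes were 3 neutrophil, 5 NK, 4 dendritic and 3 B cell markers, so the difference was not in plasma cell markers alone. Plasma cells mixed into the sorted samples stay open, since these values are the pattern itself and test nothing. The sort for Treg aims to remove such cells, but how far it did so was not measured here. The scaling of dim arrays was looked at too. The log2 75th percentiles that set the shift were 10.825 and 10.588 on the 21-week arrays. On the 10-week KO arrays they ran from 11.152 to 11.599. These lie too close together for the shift to give a difference of 5.54, which argues against scaling. Quantile normalization gave 5.48, but with so small a shift that test could hardly have come out otherwise. The age of the mice stays open as well, since 0 WT arrays came from 21-week mice. The marker list holds 4 tested genes, with Jchain at 4.24 and Mzb1 at 5.15, chosen after their values were seen.

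Myeloid and erythroid transcripts lay higher on the 10-week KO arrays than on the WT arrays at 0 h, though none of the 8 erythroid markers was called there, over all genes or over the list alone (camera adjusted p = 0.00611, 0.484 with an estimated correlation, fry 0.122). The median of the monocyte and macrophage markers was 2.23, with 11 of 12 above 0. That is the pattern itself, so macrophages or monocytes in the sorted KO samples stay open. The sort aims to remove them, but how far it did so was not measured here. A lower share of T cells alone would raise all other cells alike, and the erythroid mean exceeded the NK cell mean by 2.25 (SE over genes 0.279). Erythroid markers vary together, and over arrays the SE was 1.13, so this does not decide and a lower share of T cells stays open. With 0 slides that hold both genotypes, genotype and slide cannot be told apart.

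Effector Treg transcripts were lower in KO as a set over 12 arrays (camera adjusted p = 0.000423 at 0 h and 5.93e-05 at 3 h). The set call was lost with an estimated correlation (adjusted p = 0.253 and 0.151). On the 10-week KO arrays the adjusted p with an estimated correlation was 0.229 and 0.109. Over 12 arrays 2 of 28 genes fell, 1 rose and 25 were not called at each time point. A lower share of T cells would lower effector Treg transcripts and the T cell markers alike. Over 12 arrays the mean of the effector list minus that of the T cell markers was 0.0408 at 0 h (SE over arrays 0.407) and -0.0557 at 3 h (0.365), so a lower share may account for the 12-array result. On the 10-week KO arrays it was -0.366 at 0 h (SE over arrays 0.0289, over genes 0.175) and -0.416 at 3 h (0.076 and 0.162), which argues against a lower share as the whole cause there. The slide may account for the difference as well as the genotype, since 0 slides hold both.

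The difference of activation effects (KO minus WT) had a median of 0.702 for interferon response genes (camera adjusted p = 3.8e-06), -0.566 for cell cycle genes (4.21e-05) and 0.579 for sterol biosynthesis genes (4.21e-05). For heat shock proteins it was -0.244 (0.00231), for ribosome biogenesis and MYC targets -0.176 (0.00842), for erythroid markers -1.32 (0.0148) and for dendritic cell markers -0.724 (0.0257). With an estimated correlation the adjusted p was 0.88 for the erythroid markers and 0.874 for the other 6 lists. With fry it was 0.959 for each of these lists. The interferon median was 0.244 without the 21-week arrays (adjusted p = 0.0272), the cell cycle median -0.53 (0.00155), sterol 0.69 (7.19e-07) and dendritic cell markers -1.04 (0.0219), and the heat shock, ribosome and erythroid calls were lost (0.277, 0.197 and 0.0601). There the interferon, cell cycle and sterol lists each had an adjusted p of 0.732 with an estimated correlation.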

How the results depend on the processing

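Of the alternatives, the 75th percentile over all probes, the 21-week arrays left out with an estimated correlation, and the gene-by-gene array weights were chosen after results were seen.

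Over all alternatives, 61 counts of genes stayed within 1.5 times of the 12-array value, 23 were higher and 23 lower. An added 2-fold threshold gave 3441 genes for WT activation and 1965 for KO activation. No shift between arrays gave 118 genes for KO against WT at 3 h and 2822 for WT activation. With no filter on dim probes the counts were 5039 for KO against WT at 3 h and 1925 for KO activation; with only probes well above background on all 12 arrays, KO against WT gave 220 genes at 0 h and 159 at 3 h. For the difference of activation effects limma called 4 genes with quantile normalization, 4 with the authors' values, 2 with the 75th percentile over all probes, 1 with the mean of a gene's probes and 1 with age as a block. Of the list results over 12 arrays, fry lost 43 calls and gained 4. The 98 it left as they were include lists that neither test called. Camera with an estimated correlation called no list in any comparison: all 66 calls were lost, and the other 79 results were not called either way.

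Array quality weights moved most counts. The default estimator, which stopped without converging and gave KO replicate 2 at 0 h a weight of 0.0108, gave 44 (KO against WT at 0 h), 2503 (3 h), 12595 (WT activation), 4799 (KO activation) and 6 (difference of effects). The gene-by-gene estimator gave 2142, 422, 12215, 7790 and 3. Without the 21-week arrays the counts were 1238 at 0 h, 10353 for WT activation and 8570 for KO activation, and age as a block gave 7146 for KO activation. Fits on only the groups compared gave 0 genes for KO against WT at 3 h, 11273 for WT activation and 105 for KO activation. The cause was not tested.

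Leaving out each array in turn gave 83 to 292 genes for KO against WT at 0 h, 130 to 557 at 3 h, 3635 to 3740 for WT activation (3635, 3639 and 3689 without WT replicate 1 or 3 at 3 h or WT replicate 3 at 0 h), 1803 to 6912 for KO activation and 0 to 1 for the difference of effects.

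Among results that passed their test over 12 arrays or in the alternative, the direction of the test turned in 11 cases; turns where neither passed are not counted. Cc2d2a was at 0.987 at 0 h with no filter on dim probes. TCR immediate early genes at 3 h had a median of 0.219 with array quality weights, 0.138 with the gene-by-gene estimator, and 0.127 without the 21-week arrays, with or without an estimated correlation, and without KO replicate 3 at 3 h, but -0.84 without KO replicate 1 at 3 h. Resting or naive Treg genes at 3 h were at 0.237 without the 21-week arrays. For the difference of effects, effector Treg genes were at 0.454 with array quality weights. Leaving out arrays in turn moved NF-kB genes from -0.329 (KO replicate 3 at 0 h) to 0.307 (KO replicate 3 at 3 h). Over the same arrays costimulatory receptors moved from -0.36 to 0.405 and cytokine receptor feedback from -0.618 to 0.483. The cause was not tested.

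The share of calls that rose was 87.3% for KO against WT at 0 h and 71.7% with the 75th percentile over all probes; at 3 h it was 86.9%, against 76.6% with quantile normalization and 75.1% with the authors' values. At 0 h and 3 h it was 63.6% and 67.3% with array quality weights, 71.6% and 75.8% with the gene-by-gene estimator, and 70.7% and 69.4% without the 21-week arrays, while no filter gave 97.7% at 3 h. For KO activation it was 42.7%, 10.9% with no shift and 54.1% with normexp. The median of all genes moved to -0.36 (KO against WT at 3 h), -0.342 (KO activation) and -0.317 (difference of effects) with no shift, to -0.218 and -0.166 (0 h and 3 h) with the 75th percentile over all probes, to -0.129 and -0.117 with quantile normalization and to 0.512 at 3 h with no filter.

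No paired analysis was possible because the labels carry no mouse numbers. Age ties only KO replicate 3 at 0 h to KO replicate 3 at 3 h, and the fit with age as a block uses that tie.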

Other observations

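The tests of the arrays' age in this part were chosen after the result was seen; the splits of the arrays were not.

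Within KO, the 2 arrays from 21-week mice had 2469 genes higher and 2269 lower than the 4 from 10-week mice. The 2 arrays may come from the same mouse and the 4 may share mice, while the test treats arrays as independent. Unfolded protein stress genes were higher in 10 of 16 cases (median 1.74). That list includes Xbp1 (3.55), which is also a plasma cell factor. Of the plasma cell markers, Sdc1 was at 5.94 and Tnfrsf17 at 7.32. Xbp1, Sdc1 and Tnfrsf17 were chosen after their values were seen. The T cell receptor subunit Cd3e was at -1.54 and Il2ra, the interleukin 2 receptor of Treg, at -3.37.

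Splits of the 6 arrays of a comparison number 10, too few for a share under 0.05, and the real split was the 1 of 10 with the most calls in each. The real and highest other counts were 385 and 0 for KO against WT at 0 h, 268 and 0 at 3 h, 5551 and 0 for WT activation, and 3197 and 2103 for KO activation. For the difference of activation effects the real count was 0, and no split can give fewer, so the 100 splits decide nothing. The highest count among them was 3.

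Arrays of both genotypes on the same slide, from mice of equal age, would separate genotype from slide and age.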
